A study of Mus musculus with 2 samples.

How the data were processed

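Gene expression was measured on 2 mouse microarrays, each hybridised with RNA from pooled single muscle fibres. Per the labels, the mice were 8 males aged 6 to 8 weeks that carried 1 copy of a GFP-tagged Myh7 allele, so that fibres with slow myosin fluoresce. Fast fibres, picked for lack of GFP, came from the extensor digitorum longus (EDL), and GFP-positive slow fibres came from the soleus. The fast pool held 4447 fibres and the slow pool 1659. The tissue label of the slow sample names the EDL, while its source label and the treatment protocol name the soleus, and the soleus was taken as its origin. Muscle of origin and fibre type therefore differ together between the 2 pools. Labelling with Cy3 started from 0.1 µg of total RNA, per the labels' protocols.

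The scanner values are spot intensities on a linear scale that were background-subtracted and detrended within each array with Agilent Feature Extraction 12.0.3.1, per the file headers and the submitters' processing notes, and they were not normalized between arrays. The same deposited files give a software error of each intensity, median pixel intensities of spot and local background, and 0 or 1 flags for spots well above background, saturated or deviant. The authors' deposited value table holds linear intensities that equalled the processed intensity of the same spot times 2.83 on the fast array and 2.45 on the slow array. The medians of its columns were 30.1 and 27.1, there was no log and no centring, and what the factors scale to stays unknown.

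Control spots were left out, and 159 spots with an outlier flag on either array were removed. This left 56596 probes, of which 300 were printed 10 times and averaged. The main values were log2 processed signals minus the 75th percentile of each array, and every difference is slow minus fast. Probe accessions, without versions, were matched to a RefSeq gene table of assembly GRCm38.p6 used for names only, because the array design refers to build mm9. In all, 33763 probes (59.7%) matched 23458 genes, and 22833 probes stayed without a gene name here. For a gene with several probes, the brightest probe that was well above background on at least 1 array and not saturated was used. No spot was saturated on either array.

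A gene counted as measured where its probe was well above background on both arrays. For a gene well above background on 1 array only, a bound was computed as the bright value against the higher of the dim value and the lowest signal well above background on that array, and is written as at least N-fold. The class of a gene follows its chosen probe, and 17 of the 1161 genes of this kind in fast fibres and 14 of the 640 in slow fibres had another probe well above background on the dim array. With 1 array per group there is no replicate check and no test of any gene between the groups, and a size rule of 2-fold took its place. Resampling intervals given below cover the spread between genes only. Technical spread was taken from 288 probes printed repeatedly, whose slow minus fast difference had a median SD of 0.05 between spots. It was also taken from graded spike-in controls, of which 8 of 10 were well above background on both arrays, and from the software error, whose median was 0.20 for a difference. None of these covers variation between animals, dissections or labelling reactions. Both arrays lay on 1 slide and came from 1 scan.

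The 24 hand-made gene lists, together with cytosolic ribosomal proteins chosen by symbol, were fixed before the data were examined, as were the size rule, the rule for named genes and all alternatives but the 2 named below as added. Each list was described by the median difference of its members measured on both arrays and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Such a percentile describes these 2 arrays only. The genes named are Myh7, Myh2, Myh1 and Myh4, and up to 4 members of each list, namely the 2 highest and 2 lowest past 2-fold or, with none past 2-fold, the farthest from 0. Also named are the 10 largest differences per direction among genes measured on both arrays, and the 5 largest bounds per direction among genes well above background on 1 array. Clone-type symbols were not named, which passed over 1 gene higher in slow fibres on both arrays and 1 higher in fast fibres on 1 array. Any other gene is named as chosen after its values were seen. A gene that the rule selects is not reported here. Coordinates were not used.

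Alternatives changed the scaling (median of all probes, 75th percentile over probes well above background on both arrays, quantile normalization, or loess on mean signal with a span of 0.3). Others changed the background correction (normexp with an offset of 50, with quantile normalization or the 75th percentile), the authors' table in place of the scanner values, the filter on dim probes, the probe rule and the size rule. Normexp ran on median spot intensities, since the files hold no mean signal. Scaling to the spike-in controls, and the embryonic and denervation list without Myh8, were added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. To check the computation, 2 arrays were simulated from the fast array with noise of 0.2 added to each. On these, the size rule recovered 95 of 100 genes changed by 1.5 and 99 of 100 changed by 3 on the log2 scale. It called 2 of 13782 unchanged genes. The simulation held no variation between pools or labelling reactions and no scaling offset, so these rates do not carry over to the calls below.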

Results

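The transcriptomes of fast and slow skeletal muscle fibres of young adult male mice were compared on 2 arrays, with 1 pool of single fibres per group. The fast pool held 4447 GFP-negative fibres of the EDL, a fast muscle of the lower hind limb, and the slow pool 1659 GFP-positive fibres of the soleus, a postural calf muscle. On the fast array 30997 of 59305 spots (52.3%) were well above background, and on the slow array 30206 (50.9%). Of 23458 genes with a probe, 12846 were measured on both arrays by the chosen probe, 1161 were well above background in fast fibres only and 640 in slow fibres only, while 8811 were not well above background on either. There were no replicates, so each value below is a difference between 2 pools without a replicate check, and the number of arrays limits the precision.

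The myosin heavy chains, the motor proteins that define fibre types, separated the pools. Myh7, the slow type I heavy chain whose GFP tag guided the picking, was 270-fold higher in slow fibres, at a log2 level of 10.66 against 2.58. Myh4, the type IIB chain of the fastest fibres, was 2981-fold higher in fast fibres, and Myh1, the type IIX chain, was 115-fold higher there. Myh2, the type IIA chain, was 3.59-fold higher in fast fibres and stood at 7.66 in the fast and 5.82 in the slow pool. Its other probe gave a log2 difference of -1.39. The SD of a difference between repeated spots had a median of 0.05 on the log2 scale.

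Among the 14647 genes measured on at least 1 array, 1570 (10.7%) were at least 2-fold higher in slow fibres and 2100 (14.3%) at least 2-fold higher in fast fibres. The largest slow-fibre differences belonged to contractile genes, with Tnnc1, the slow and cardiac troponin C, 898-fold higher, Myh7b, a slow-type myosin, 643-fold, and Tnni1, the slow troponin I, 551-fold, with a log2 difference of 9.91 by another Tnni1 probe. Tpm3, the slow tropomyosin, was 536-fold higher by its brightest probe, while its other probes measured on both arrays ran down to a log2 difference of 1.30. Besides contractile genes, the 10 largest included Rspo3, a secreted enhancer of Wnt signalling, at 79.3-fold. They also included C1d, a cofactor of the nuclear exosome, at 141-fold by 1 probe and a log2 difference of 0.64 by its other probe. Myh13, the extraocular myosin, was 133-fold higher in slow fibres by its only probe. Higher in fast fibres were Pvalb, the calcium buffer parvalbumin, at 1515-fold, Myom2, an M-band protein, at 605-fold, and Pcsk1n, which encodes the proprotein convertase inhibitor proSAAS, at 324-fold. Actn3, the fast-fibre alpha-actinin, was 214-fold higher there, and Tmem233, Parm1 and Exoc3l4 were 114-fold, 109-fold and 99.6-fold higher. Kcnc4, a voltage-gated potassium channel, was 104-fold higher in fast fibres by the chosen probe, and its other probe, for a predicted transcript, gave a log2 difference of -0.41.

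Genes whose chosen probe was well above background in 1 pool added further contrasts. Mybpc2, the fast myosin-binding protein C, was at least 11769-fold higher in fast fibres. Tspan8, a tetraspanin, was at least 224-fold, Fam83g at least 188-fold, Itga4, an integrin subunit, at least 129-fold and Mdga1 at least 103-fold higher there. A second Itga4 probe was not well above background on either array, and a second Mdga1 probe, measured on both arrays, gave a log2 difference of -4.36. In slow fibres Tecrl was at least 322-fold, Csn1s2b, a casein gene, at least 143-fold, Dmkn at least 135-fold, Lgi1 at least 111-fold and Cyfip2, a regulator of actin assembly, at least 86.7-fold higher. Under normexp, which shrinks differences that involve dim probes, the log2 values nearest to 0 were 5.45 for Tecrl, 4.25 for Csn1s2b, 4.14 for Dmkn, 3.93 for Lgi1 and 3.37 for Cyfip2. They were -10.53 for Mybpc2, -4.94 for Tspan8, -4.77 for Fam83g, -4.03 for Itga4 and -3.17 for Mdga1, and Csn1s2b was at 4.99 by the median over its probes. Of the 90 genes that the naming rule selects, 31 moved by over 1.5 times under normexp, among them Tnnc1 to 9.20, Myh7b to 8.69 and Rspo3 to 4.95. Of those higher in fast fibres, Myh4 moved to -10.31, Myom2 to -8.56, Pcsk1n to -7.22, Exoc3l4 to -5.41, Parm1 to -5.16, Kcnc4 to -4.82 and Tmem233 to -4.64.

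Slow fibres held 42.8% of all genes past 2-fold, and 71.0% (3178 against 1300 genes) under scaling to spike-in controls, an alternative that adds 0.43 to every log2 difference and was chosen after seeing the data. The authors' table shifted the median of all genes by -0.11, to a split of 36.7%, and the remaining scalings shifted it by less than 0.1. Under normexp with quantile normalization, 771 genes were at least 2-fold higher in slow fibres and 1005 in fast fibres. Of the genes measured on both arrays, 677 were at least 2-fold higher in slow fibres under all 9 scalings and 717 in fast fibres. These 9 are the main scaling, its alternatives, spike-in scaling, the authors' values and both normexp settings, which also change the background correction. Of all slow and fast calls, normexp with quantile normalization kept 48.7% and 47.2%, and normexp with the 75th percentile 49.2% and 47.7%. Spike-in scaling kept 61.9% of fast calls. The other scalings kept at least 87.1% of slow and 95.5% of fast calls. The 677 and 717 thus do not reflect scaling alone.

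**Figure D1:**
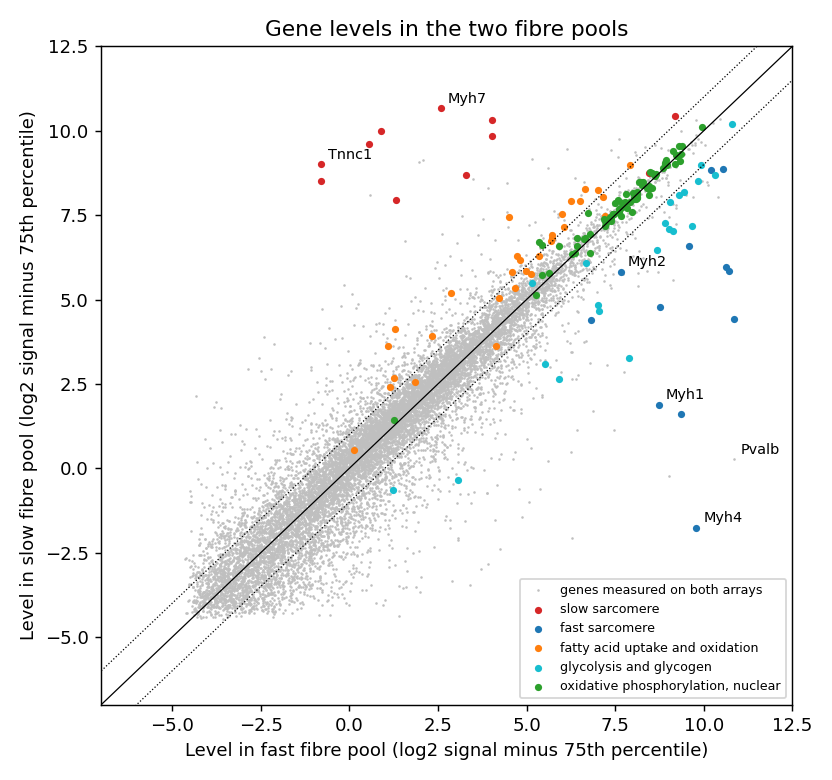
Log2 level in the fast pool (horizontal axis) against the slow pool (vertical axis), each as log2 signal minus the 75th percentile of the array, for the 12846 genes measured on both arrays (grey) with members of 5 gene lists coloured. The solid line marks equal levels and the dotted lines 2-fold differences. Slow sarcomere genes lie above the upper dotted line with 1 exception of 11, and all fast sarcomere genes shown lie below the lower one.

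Sarcomere genes parted almost completely by fibre type. Of 11 slow sarcomere genes, 10 were at least 2-fold higher in slow fibres, and the list median was 6.64, or 99.4-fold, which is also the value of the light chain gene Myl6b. All 13 fast sarcomere genes were at least 2-fold higher in fast fibres, with a median of -4.34 over the 12 measured on both arrays. Both lists lay beyond all random lists, at percentiles 100 and 0, and each kept its direction under every scaling.

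Calcium handling genes divided within the list. Atp2a2, the slow and cardiac calcium pump of the sarcoplasmic reticulum, was 182-fold higher in slow fibres by its brightest probe, with log2 differences of 8.08 and 5.33 by its other probes, and Sln, which encodes the pump inhibitor sarcolipin, 33.6-fold. Atp2a1, the fast-fibre pump, was 7.40-fold higher in fast fibres, as was Pvalb by the value given above. Of 23 members, 3 were at least 2-fold higher in slow fibres, 7 in fast fibres and 13 were not called. Among the 13 was a gene well above background in slow fibres only, at least 1.7-fold higher there. Over the scalings, 6 to 12 members measured on both arrays were past 2-fold in fast fibres. The median was -0.84, at percentile 0.

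Energy metabolism genes differed by pathway. Glycolysis and glycogen genes were higher in fast fibres, 17 of 21 by at least 2-fold, with a median of -1.85. Gpd1, the glycerol-3-phosphate dehydrogenase of the cytosol, was 24.9-fold higher in fast fibres, and Pfkfb1, which makes and degrades a fructose bisphosphate that activates glycolysis, 10.6-fold. Genes of fatty acid uptake and oxidation were higher in slow fibres, 20 of 30 by at least 2-fold and none by as much in the other direction, with a median of 1.21. Lpl, the lipase that frees fatty acids from lipoproteins, was 7.73-fold higher and Cd36, a fatty acid transporter, 7.19-fold. Both directions held under every scaling, with 13 to 18 glycolytic and 16 to 27 fatty acid genes past 2-fold.

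Nuclear genes of oxidative phosphorylation were at nearly equal levels, with 76 of 78 measured members within 2-fold and an SD over members of 0.27. Their median of 0.08 lay at percentile 86.6 of random lists, and was below 0 under loess and in the authors' table and 0.50 under spike-in scaling. Cox8a and Cox6a1, the ubiquitous forms of cytochrome c oxidase subunits, were 2.53-fold and 2.28-fold higher in slow fibres, the latter with a log2 difference of 0.98 under normexp with quantile normalization. Citric acid cycle and pyruvate dehydrogenase genes had a median of 0.01 (percentile 47.0), below 0 under 5 scalings, with 15 of 17 members within 2-fold. The exceptions were Idh2, the NADP-dependent mitochondrial isocitrate dehydrogenase, 9.84-fold higher in slow fibres (a log2 difference of 4.42 by its other probe), and Idh3a, a subunit of the NAD-dependent enzyme, 2.08-fold higher in fast fibres but at -0.62 under spike-in scaling. The 13 genes of mitochondrial DNA had no matched probe and were not analysed here.

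Transcriptional regulators of fibre type went both ways, with 8 of 38 at least 2-fold higher in slow fibres, 6 in fast fibres and 24 within 2-fold. Esrrb and Esrrg, nuclear receptors that act on oxidative metabolism genes, were 26.8-fold and 14.3-fold higher in slow fibres, Esrrb with a log2 difference of 4.08 under normexp. Maf, a large Maf factor linked to type IIB fibres, was 24.7-fold higher in fast fibres, and Myod1, a myogenic factor enriched in fast muscle, 18.2-fold. The median of 0.07 (percentile 46.6) was below 0 under loess and in the authors' table, and 0.50 under spike-in scaling, with 11 members past 2-fold in slow fibres and 5 in fast fibres. Of 19 limb position and homeobox genes above background, 3 were at least 2-fold higher in each pool and 13 were not called. Among the 13 was a gene well above background in fast fibres only, at least 1.32-fold higher there. Hoxd8 and Hoxd9 were 3.91-fold and 3.89-fold higher in slow fibres, whereas Meox2 and Hoxa13 were 2.61-fold and 2.34-fold higher in fast fibres. All but Hoxd8 were within 2-fold under normexp with quantile normalization and with the 75th percentile, and the log2 differences nearest to 0 were 0.51 for Hoxd9, -0.33 for Hoxa13 and -0.95 for Meox2. Their median was -0.22 (percentile 11.8), and 0.21 under spike-in scaling, with 4 members past 2-fold in slow fibres and 0 in fast fibres.

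Genes of the Z-disc and mechanical stress response also diverged. Pdlim1, a PDZ and LIM domain protein, was 21.0-fold higher in slow fibres (a log2 difference of 5.03 by its other probe), and Ankrd2, a titin-associated ankyrin repeat protein, 16.3-fold. Its relative Ankrd1 was 29.7-fold higher in fast fibres and the small heat shock protein gene Hspb8 3.38-fold. Of 24 members, 7 were at least 2-fold higher in slow fibres, 4 in fast fibres and 13 within 2-fold, with a median of 0.52 at percentile 100. Under spike-in scaling these were 11 and 3 members, with a median of 0.95.

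Neuromuscular junction genes held 5 of 13 members at least 2-fold higher in slow fibres and 4 in fast fibres. Colq, the collagen tail of acetylcholinesterase, and Musk, the receptor kinase of the synapse, were 3.29-fold and 2.75-fold higher in slow fibres. Ache, the esterase itself, was 6.42-fold higher in fast fibres, and Ufsp1 3.17-fold. The median was -0.22 (percentile 7.31), and 0.21 under spike-in scaling, and over the scalings 2 to 5 members were past 2-fold in slow fibres and 2 to 4 in fast fibres. Of 11 embryonic and denervation genes above background, 4 were at least 2-fold higher in slow and 6 in fast fibres, with a median of -1.94 at percentile 0. The median was -1.12 without Myh8, the neonatal myosin, left out after its values were seen because its second probe was not well above background on either array. Myh3, the embryonic myosin, was 33.1-fold higher in slow fibres by the chosen probe and at least 1.5-fold by its second probe. Hdac9, a class II histone deacetylase, was 4.60-fold higher in slow fibres. Actc1, the cardiac actin of developing muscle, and Dlk1, an imprinted Notch ligand relative, were 11.8-fold and 7.72-fold higher in fast fibres. Under normexp the log2 differences nearest to 0 were 1.24 for Hdac9 and -1.76 for Dlk1.

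Atrophy and proteolysis genes lay within 2-fold for 16 of 19 members, with a median of -0.01 (percentile 36.1), above 0 under median scaling, normexp with the 75th percentile and spike-in scaling. The ubiquitin ligase gene Trim63 was 4.16-fold higher in fast fibres and the metallothionein gene Mt2 2.46-fold, while the mitophagy receptor gene Bnip3 was 3.64-fold higher in slow fibres. Of 20 immediate early and dissociation stress genes, 8 were at least 2-fold higher in fast fibres, with Egr2 at 6.27-fold and Ier3 at 4.17-fold. The 3 heat shock members were higher in slow fibres, among them Hspa1a at 3.18-fold and Dnajb1 at 2.95-fold. The list median was -0.68, at percentile 0, and under spike-in scaling 5 members were past 2-fold in fast fibres and 3 in slow fibres.

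Markers of other cell types in muscle were mostly lower in the slow pool, beside the fibre genes described above. Endothelial markers were at least 2-fold higher in fast fibres for 10 of 11 members, with Emcn 3.64-fold higher and Cldn5, a tight junction protein, at a log2 difference of -3.90, and a median of -1.48. Fibroblast markers were at least 2-fold higher in fast fibres for 10 of 11 members, with Col1a1, a collagen chain, at 4.54-fold and Dpt at least 4.21-fold, and a median of -1.77. All 6 erythrocyte markers above background were higher there, with the globin genes Hba-a2 and Hba-a1 at 2.75-fold and 2.70-fold and a median of -1.33. These 3 lists lay at or below percentile 0.80. Under spike-in scaling, 6 of the 11 endothelial, 7 of 10 fibroblast and 2 of 5 erythrocyte markers measured on both arrays were past 2-fold.

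Schwann cell markers had 5 of 8 members at least 2-fold higher in fast fibres, including Prx at 3.97-fold (a log2 difference of -1.21 under normexp), with a median of -1.30 (percentile 0.28). Pmp22 was 3.91-fold higher in slow fibres by its brightest probe, with a log2 difference of 1.26 by its other probe, and Mbp 4.98-fold by its brightest probe, with the opposite direction for the median over its probes. Smooth muscle and pericyte markers had a median of -0.92 (percentile 0.70), with Rgs5 and Notch3 at 3.07-fold and 2.41-fold higher in fast fibres and Cspg4 2.36-fold higher in slow fibres. Tendon markers had a median of -0.91 (percentile 1.23), with Fmod and Tnmd at 4.17-fold and 2.79-fold higher in fast fibres, but Scx, the tendon transcription factor, 4.13-fold higher in slow fibres. Over the scalings, 2 to 5 Schwann cell and 1 to 5 smooth muscle and pericyte markers were past 2-fold in fast fibres.

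Immune markers had 3 of 9 members at least 2-fold higher in fast fibres, among them the macrophage genes Cd68 at 4.42-fold and Mrc1 at a log2 difference of -1.58. The median was -0.48 (percentile 8.12) over the 6 members measured on both arrays, 2 of them above 0. It was -0.14 over all 9 with members at their bound. That value is itself the bound of a gene well above background in fast fibres only, so the median could lie lower. A further 5 members were not well above background on either array. Of 3 adipocyte markers above background, Fabp4 was 2.30-fold higher in fast fibres, and the median of the 2 measured on both arrays was -0.50, above 0 with no filter on dim probes. Satellite cell markers had a median of 0.37 over 4 members (percentile 81.0), while Chrdl2 at least 4.16-fold and Vcam1 3.28-fold were higher in fast fibres. Cytosolic ribosomal protein genes lay within 2-fold for 74 of 75 members, with a median of 0.28 (percentile 100) and Rpl3 2.23-fold higher in slow fibres. All lists from the endothelial to the ribosomal one kept the sign of their median under every scaling.

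**Figure D2:**
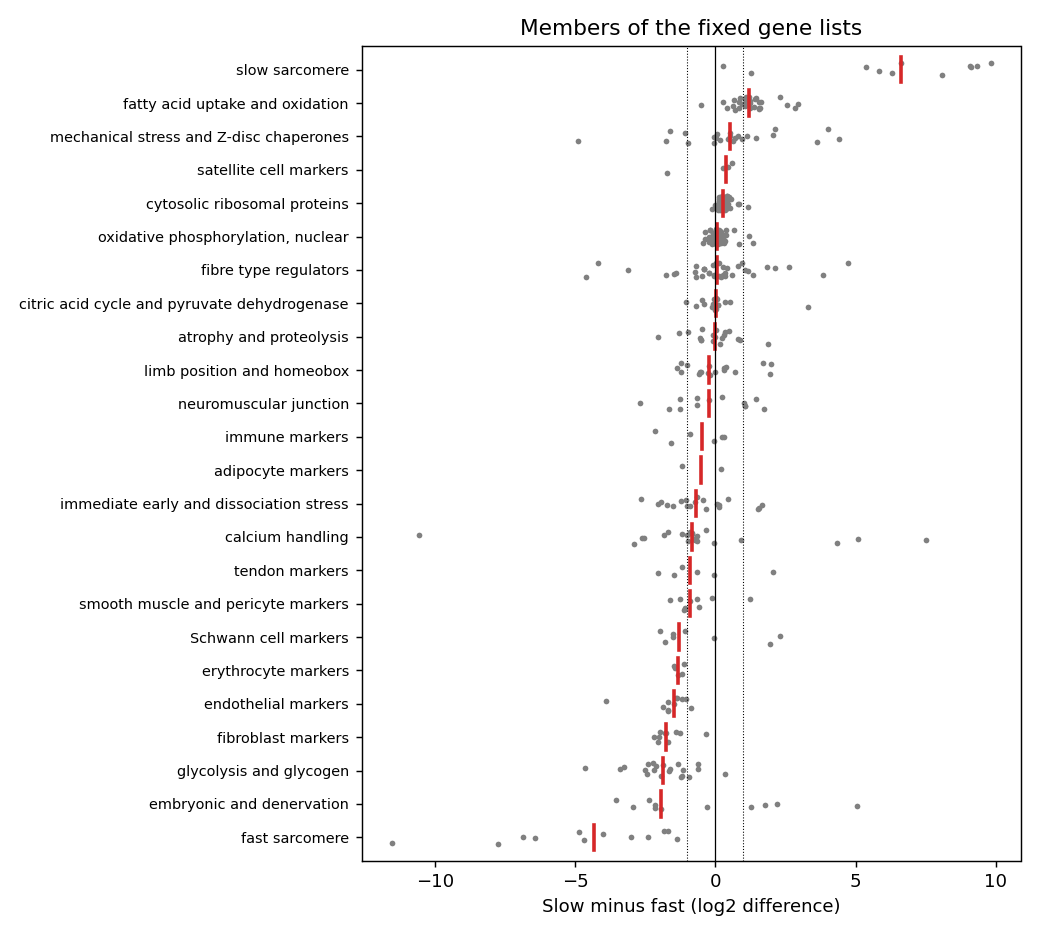
Slow minus fast log2 difference (horizontal axis) of each member of the gene lists measured on both arrays (grey points), with the list median as a red bar. Dotted lines mark 2-fold differences. Medians run from -4.34 for fast sarcomere genes to 6.64 for slow sarcomere genes, and those near 0 (oxidative phosphorylation, citric acid cycle, fibre type regulators, atrophy, homeobox, neuromuscular junction) change sign under some scalings.

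Of the 23 lists with a percentile, 4 lay in the upper 2.5% and 11 in the lower 2.5% of random lists. Lists of unrelated genes would place 1.15 in both tails together. Members of a list can vary together, while random lists draw genes singly, so these counts are no test against chance. Both sarcomere lists hold fibre type genes, Myh7 among them, so their places in the tails were largely set by the choice of members. Of the 90 rule-selected genes, all past 2-fold, 14 were within 2-fold or turned under at least 1 alternative. Besides those given above, these were Chrdl2, Dpt, Cspg4, Tnmd, Vcam1 and Mbp under normexp, and Fabp4, Mt2 and Notch3 under spike-in scaling. Differences of single genes rested on probe choice to a degree. Of 784 genes past 2-fold with several probes measured on both arrays, 715 (91.2%) had all probes in 1 direction and 527 (67.2%) had all of them past 2-fold.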

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

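No test here was chosen after the result was seen, and the signals below lie outside the gene comparisons. Among 22833 probes without a gene name, 9196 were well above background on at least 1 array. Of these, 1129 were at least 2-fold higher in slow fibres and 1086 at least 2-fold higher in fast fibres. Of 96 external control probes for RNA standards, 94 were not well above background on either array. A first exception had a median signal of 21.0 on the fast array, well above background in 28 of 28 spots, and 2.16 on the slow array, well above background in 0. Another had a median signal of 23.5 on the fast array and 22.8 on the slow array.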

How the results depend on the processing

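Spike-in scaling and leaving Myh8 out of its list were chosen after seeing the data, and all other alternatives before. Signal over background limits the dim genes, and leaving out a replicate was not possible with 1 array per group. Leaving out saturated probes, or using the brightest probe whether saturated or not, changed nothing because no spot was saturated. No paired analysis was possible because each group has 1 array.

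The genes at least 2-fold higher in slow fibres and the genes at least 2-fold higher in fast fibres numbered 771 and 1005 under normexp with quantile normalization, and 782 and 1002 under normexp with the 75th percentile. The offset of 50 in normexp shrinks differences of dim probes by construction. Of the 1570 and 2100 calls, 764 and 992 were kept in the first setting. Spike-in scaling gave 3178 and 1300 genes, the 4-fold rule 490 and 641, and no filter on dim probes 2494 in slow fibres. Under the other settings both counts stayed within 1.5 times the main ones.

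Myh7 slow minus fast was 8.16 under quantile normalization, 7.91 under loess, 8.15 and 8.02 under normexp with quantile normalization and the 75th percentile, 7.97 in the authors' table and 8.51 under spike-in scaling. The median of slow sarcomere genes was 6.50 under loess, 6.50 and 6.53 under the normexp settings, 6.53 in the authors' table and 7.07 under spike-in scaling. The median of fast sarcomere genes was -4.24 under quantile normalization, -4.53 under loess, -4.29 under normexp with quantile normalization, -4.45 in the authors' table and -3.91 under spike-in scaling. It was -4.68 with no filter or with members at their bound, which adds Mybpc2. Only Mbp slow minus fast reversed among named genes, to -0.88 for the median over its probes, and the cause was not tested. Of the other values of named genes under these alternatives, 600 stayed within the spot SD of 0.05 and 468 moved beyond it in the same direction. Of the list medians, 177 stayed within it and 136 moved, and 17 values of 7 lists changed sign, namely of the 6 lists near 0 and, with no filter on dim probes, the adipocyte list. The immune list passed below percentile 2.5 with the median over probes, and no list left the tails in any setting run.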

Other observations

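All tests in this part but the comparison of dimmer with brighter oxidative phosphorylation genes were chosen after the result was seen. The genes of the next 2 paragraphs were also chosen after their values were seen.

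Slc16a3, the lactate exporter of glycolytic cells, was 36.2-fold higher in fast fibres, while Slc16a1, the lactate importer, lay within 2-fold at a log2 difference of 0.99. Ldhb, the heart-type lactate dehydrogenase subunit, was 16.3-fold higher in slow fibres, and Ldha, the muscle-type subunit, 2.35-fold higher in fast fibres. Bdh1, a ketone body enzyme, had a log2 difference of 4.64. Car3, the carbonic anhydrase of slow muscle, was 9.98-fold higher in slow fibres, and Mb, the oxygen carrier myoglobin, 2.52-fold. Gpd2, the mitochondrial partner of Gpd1 in the glycerol phosphate shuttle, was 42.2-fold higher in fast fibres. The sodium pump beta subunits parted, with Atp1b2 41.9-fold higher in fast and Atp1b1 4.75-fold higher in slow fibres. Mstn, the growth inhibitor myostatin, was at least 89.0-fold higher in fast fibres.

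Among regulators, Ppara, a receptor for fatty acids, was 6.23-fold higher in slow fibres, while Ppargc1a, a coactivator of mitochondrial genes, lay within 2-fold at a log2 difference of -0.71. Sox6, a repressor of slow genes, and Tbx15, a factor of glycolytic fibres, were 8.62-fold and 3.40-fold higher in fast fibres. Prox1 and Vgll2 were 4.34-fold and 3.60-fold higher in slow fibres.

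Markers of other cell types were mostly lower in the slow pool. Their pooled median was -1.33 over 55 genes of 7 lists with at least 5 measured members, 49 of them below 0. The satellite cell list, with a median of 0.37 over 4 measured members, and the adipocyte list, with -0.50 over 2, were thereby left out. The scaling of the arrays is unlikely as the whole cause, since the pooled median stayed at or below -0.82 under all 9 scalings. More cells of all other types in 1 proportion could not be judged. The fibroblast median, with members at their bound, lay at -0.62 from that of the other lists (95% interval from resampled genes, adjusted over 8 lists, -1.33 to -0.02). The intervals of 7 lists held 0. Among them were satellite cells with a gap of 1.54 and immune markers with 1.24, the latter from a median that is itself a bound. These intervals cover the spread between genes of 1 pair of arrays and not the variation between pools. More cells of several other types in the fast pool may account for the pattern but cannot be told apart from a difference between EDL and soleus, which differ together with the pools, and the labels name no sort against attached cells. No gene stood on more than 1 list, how many are also expressed by muscle fibres was not tested, and the abundant markers Col1a1 and Hba-a1 stood at 5.39 and 5.44 in fast and 3.21 and 4.01 in slow fibres.

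Oxidative phosphorylation genes had nearly equal levels while the median of fatty acid oxidation genes was 1.14 higher than theirs. Compression of bright signals was not seen within the oxidative phosphorylation list. Its 39 dimmer genes had a median only 0.067 above that of the 39 brighter genes (95% resampling interval over genes -0.02 to 0.16). The median levels of these groups, 7.29 and 8.64, were both above the 5.50 of the fatty acid oxidation genes. Compression relative to the fatty acid oxidation genes therefore cannot be excluded by this comparison. The spike-in controls at fast levels of 0.47 to 7.61 gave slow minus fast differences of -0.43 to -0.46. Brighter ones, at 8.32 and 10.32, gave smaller differences of -0.37 and -0.24, and the dimmest, at -2.56, gave -0.33. Some compression at the brightest levels thus stays open. The scaling of the arrays cannot be told apart from a true equality for the level itself, since the oxidative phosphorylation median was 0.50 under spike-in scaling and no other reference for total RNA was used here. A fibre type difference in a part of oxidative metabolism stays open and untested. The EDL pool also held type IIA and IIX myosin signal, and the slow soleus pool held Myh2 signal at a level of 5.82.

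Developmental and extraocular myosins gave signals that may come in part from related myosin transcripts. For Myh8, the neonatal myosin, chosen after its values were seen, the chosen probe was 5.19-fold higher in fast fibres. Its second probe reached at most -6.78, under the lowest levels well above background of -4.66 and -4.48, which is consistent with cross-hybridisation of the chosen probe, although a second probe that fails to bind stays open. For Myh3 the second probe gave at least 0.59 more in slow fibres, and for Myh13 the only probe gave 7.05, so cross-hybridisation cannot be told apart from expression, because no probe sequences were used here. A true difference in these genes between the pools stays open and untested.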
